A study of Mus musculus with 8 samples.

How the data were processed

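Gene expression was measured in neural tube tissue of FVB mouse embryos at day 8.5 of gestation. Per the labels' protocols, the tissue was cut by laser microdissection from cryosections just in front of closure site 1, where the neural tube was still open, and just behind it, where it had closed. Embryos came from diabetic or from normal dams. Total RNA was prepared with Trizol, and 7 ng per library went into barcoded SOLiD SAGE libraries, which count one short tag near the 3′ end of each transcript. Library totals ran from 5041586 to 16655583 counts. Crossing region with dam gives 4 groups of 2 libraries each, 8 libraries in all.

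The values are raw tag counts per gene symbol, as deposited in 1 file per library. The mouse genome build was mm9, per the submitters' processing notes. The aligner, the counting program, the annotation release, the treatment of tags that fit several genes and the use of strand are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, and overlapping or antisense genes are therefore uncertain. Each file lists the same 26608 genes, of which 15162 had a count in at least 1 library, and no row lacked a gene name. There were 25 names that a spreadsheet had turned into dates, and these were kept as they stand. Symbols were compared with reference tables of assembly GRCm38.p6 for names only: 21242 were current, 2275 were older synonyms and 3091 had no match. No coordinates are given because that assembly is not the build of the counts.

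Groups were taken from the sample labels, and the numbers in the sample titles (09 to 16) serve as library names. No number occurs in more than 1 group, so no pairing was fitted. The labels do not say how many embryos or litters a library holds, or whether open and closed tissue came from the same embryos. The p-values measure only the spread between these libraries, and they can be too small or too large where libraries share an animal.

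Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total count 15), which left 11779, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test with a Benjamini-Hochberg adjusted p below 0.05. Closed against open tissue and diabetic against normal dams were tested in an additive model of region and dam. The 4 simple differences and the interaction were contrasts in a model of the 4 groups. Levels are CPM from edgeR on TMM-scaled library sizes, given as mean ± SD. A standard error of a log2 fold change is the one implied by the F statistic. Where every library of a group was at 0, a bound on the fold uses 3 counts over the group, which covers counting error only. A list median with bounds sets such members to their bound and leaves out members with at most 3 counts in each of both groups.

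A set of 34 gene lists covered the cell types that such sections can hold, axial level, signalling, stress and metabolism, and genes whose mouse mutants have neural tube closure defects. The list of mitochondrially encoded genes found no member, which left 33 lists. Each was tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 33 lists within a comparison. A list score per library is the mean over members of log2 CPM (prior count 2), centred on the mean of the 8 libraries. Groups, comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined.

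The rule named the genes past the threshold with the highest and lowest log2 fold changes and a mean of at least 10 counts (up to 12 in each direction in an additive comparison and up to 5 in a contrast). Where none passed, it named the 3 with the smallest p in each direction, as values only. It also named up to 4 members per list past the threshold, otherwise the 2 members with the highest mean count, and always Pax3, Vangl2, Grhl3, Cdx2, Slc2a2 and Sox2, together with sex-linked and the most abundant genes. Other genes outside this rule are said to have been chosen after their values were seen.

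The gene tests and camera were tested on simulated counts, for 2 of the comparisons, with the real means, dispersions and library sizes and 200 changed genes. For closed against open tissue, with 11005 genes tested, edgeR recovered 3.03% of 66 genes changed by 1 on the log2 scale, 53% of 66 changed by 2 and 72.1% of 61 changed by 4, with 3 false calls. DESeq2 made 51 false calls among 151 calls on the same counts, and limma-voom 4 among 78. For closed against open tissue of normal dams, with 11039 genes tested, edgeR recovered 1.54%, 19% and 46.9% at these sizes, with 4 false calls. A simulated list of 20 genes raised by 1 was found in both designs, and none of the 33 other lists passed. The simulated genes vary independently, which real genes do not.

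The alternatives were DESeq2's size factors, total counts alone, no filter, a mean of at least 50 counts, DESeq2, limma-voom, each library left out, models of fewer libraries or without the other factor, and an estimated correlation for the lists. After seeing the data, fits without diabetic open library 14 and normal open library 10, which had the most genes at 0, and without the 2 libraries with high Xist were added. Some results for single genes are not reported here.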

Results

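Tag counts were obtained from 8 libraries of laser-dissected neural tube at day 8.5 of gestation, the stage at which the mouse neural folds meet. There were 2 libraries each of open and of closed neural tube from normal and from diabetic dams. Totals ran from 5041586 counts in diabetic closed library 15 to 16655583 in diabetic open library 13, and 9920 to 12924 genes had a count in a library. The most abundant gene took between 1.22% and 1.85% of a library's counts and was Tubb5, Tpt1, Ldha or Crabp1.

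Levels of several neural genes set 1 library apart. Sox2, a transcription factor of neural progenitors, ranged from 276 to 560 CPM in 7 libraries and stood at 30.2 CPM in diabetic open library 13. That library also had low Pax3 (7.59 CPM) and Hes5 (13.6 CPM). Sox11 and Lin28a, the most abundant genes of the neural progenitor list, were not low in the same way: Sox11 was highest there (2691 CPM, 1708 to 2566 elsewhere) and Lin28a stood at 1534 CPM (1617 to 2472 elsewhere). The library had the highest levels of Pdgfra, a receptor of mesenchymal cells (466 CPM), Twist1 (310 CPM) and Tek, an endothelial receptor (104 CPM). Twist1 was chosen after its values were seen. Gata4, a factor of heart and endoderm, reached 86 CPM in it and at most 4.44 CPM elsewhere. Xist, the RNA that silences an X chromosome in females, stood at 290 CPM in normal open library 10 and 305 CPM in normal closed library 12. Ddx3y, a Y-linked gene, was at 0.849 and 0.456 CPM in these libraries and at 192 to 279 CPM in the other 6. All 4 libraries of diabetic dams were thus of the Ddx3y kind, against 2 of the 4 of normal dams.

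Libraries of a group were about as alike as libraries of different groups. The correlation of log2 CPM across genes was 0.818 to 0.941 (median 0.855) for the 4 pairs within a group and 0.776 to 0.929 (median 0.864) for the 24 other pairs. Of 9490 genes with at least 50 counts in diabetic open library 13, 11.9% had no count in library 14 of the same group. The figure was 6.44% for normal open library 10 against library 09, and at most 1.22% within the closed groups. No 2 libraries agreed within sampling noise. The biological coefficient of variation was 0.894 in the additive model and 0.859 in the model of 4 groups.

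**Figure D1:**
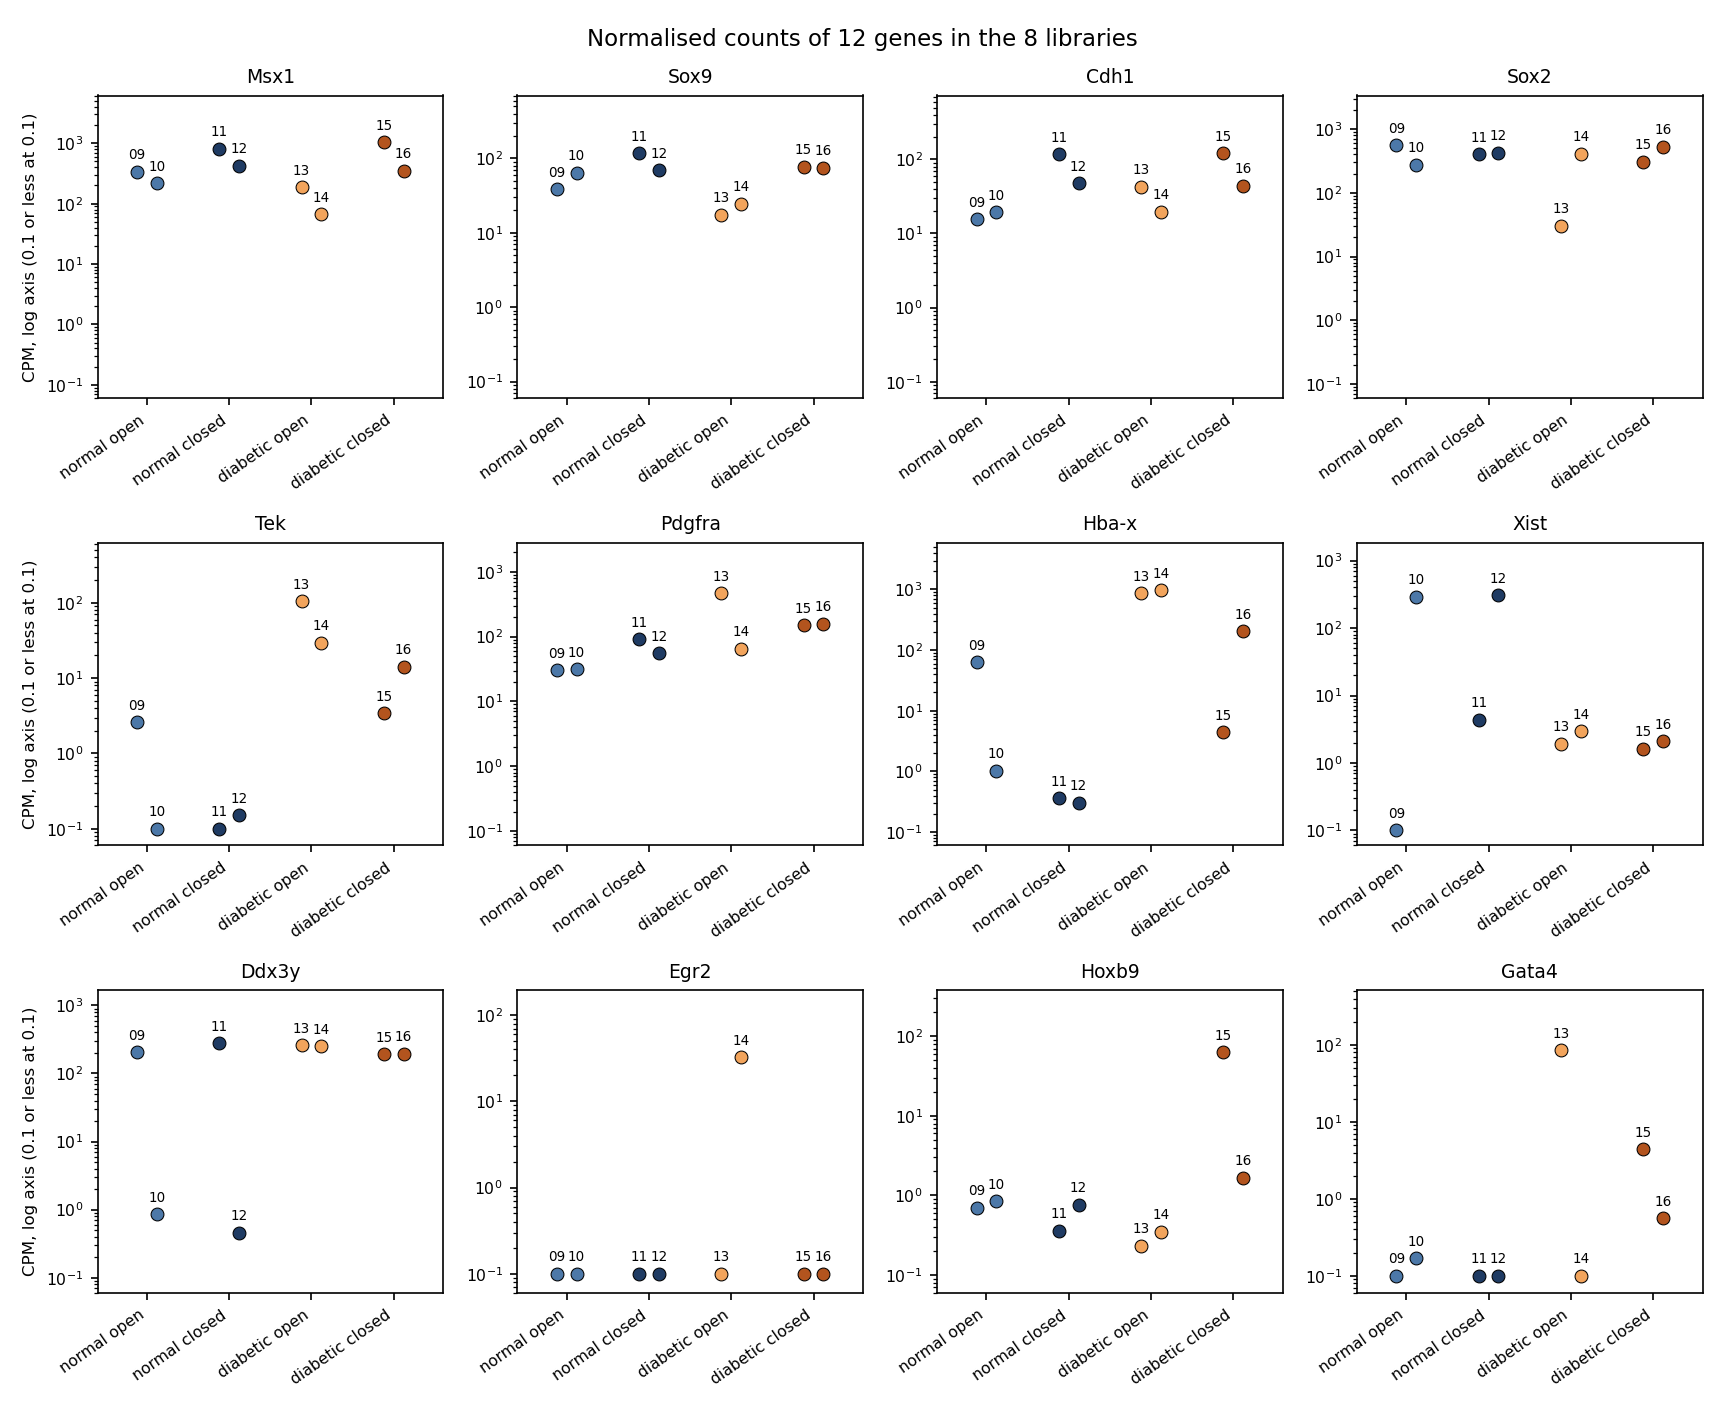
Each point is one library, labelled with its number, for 12 genes in the 4 groups (x axis). The y axis is CPM on a log scale, with values of 0.1 or less drawn at 0.1. Msx1 and Cdh1 were higher in all 4 closed libraries than in all 4 open ones, and Sox2 was at 30.2 CPM in diabetic open library 13.

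The first comparison asked what distinguishes neural tube that has just closed from the tissue still open in front of it. These regions also differ in axial level, so a difference cannot be assigned to closure itself. Genes of the dorsal neural tube and neural crest ranked higher in closed tissue by camera at its preset correlation, and not at an estimated one (adjusted p = 0.279). The dorsal midline factor Msx1 stood at 654 ± 321 CPM in closed and 202 ± 111 CPM in open tissue (SD, n = 4 each), a log2 fold change of 1.80 (SE 0.46). Sox9, a neural crest factor, stood at 84.7 ± 21.9 and 36.4 ± 20.8 CPM, and Cdh1, the epithelial E-cadherin of surface ectoderm, at 82.5 ± 42.3 and 24.3 ± 12.3 CPM. Each of these was higher in 4 of 4 closed libraries than in any open one. None passed the edgeR test over all genes (adjusted p = 1.00), DESeq2 called Msx1, and Sox9 was chosen after its values were seen.

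Of 23 measured genes of the dorsal neural tube and neural crest, 16 had a positive fold change, with a median of 0.87 on the log2 scale (camera adjusted p = 0.000141). The adjusted p was 0.279 with an estimated correlation. Msx1 and Sox9 passed when adjusted over the list alone (0.0284 each). Over all genes 0 members passed by edgeR, while DESeq2 called Msx1 (adjusted p = 0.0163) and Tcfap2a (0.0471). The 2 most abundant members were Msx1 and Crabp1, and Crabp1 stood at 3629 ± 1899 CPM in closed and 8316 ± 6546 CPM in open tissue. The surface ectoderm list had 13 of 16 members positive, with a median of 1.32 (adjusted p = 0.000141, and adjusted p = 0.602 with an estimated correlation). Its keratin Krt18 stood at 46.8 ± 29.6 and 69.4 ± 82.2 CPM. Tcfap2a, a factor of neural crest and surface ectoderm that belongs to both lists, was at 26.2 ± 12.4 CPM in closed and 4.99 ± 6.26 CPM in open tissue. It was chosen after its values were seen. The endothelium list ranked lower in closed tissue, with 12 of 15 members negative and a median of -0.999 (adjusted p = 0.000687, and adjusted p = 0.602 with an estimated correlation). Egfl7, secreted by endothelium, stood at 42.1 ± 12.8 and 81.3 ± 43.3 CPM. Without diabetic open library 13 the endothelium list was no longer past the threshold (adjusted p = 0.137).

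The other 30 lists did not pass in this comparison. The embryonic globin Hba-x stood at 52.2 ± 101 CPM in closed and 479 ± 518 CPM in open tissue, and it passed when adjusted over the list of primitive blood cells alone (0.0486). Gli1, a transcriptional readout of Hedgehog signalling, stood at 393 ± 43.4 and 239 ± 37.3 CPM and passed when adjusted over its list alone (0.022). The 79 measured genes whose mutants have closure defects had a median of 0.08 (adjusted p = 0.626). Pax3, mutated in the Splotch mouse, was at 91.7 ± 37.5 CPM in closed and 51.8 ± 42.6 CPM in open tissue. The planar polarity gene Vangl2 was at 12.9 ± 4.33 and 13.1 ± 10.4 CPM, and Grhl3 at 4.38 ± 1.51 and 5.30 ± 1.21 CPM. Caudal progenitor genes had a median of 0.83 (adjusted p = 0.101), and Cdx2 was at 3.74 ± 3.93 and 1.92 ± 1.63 CPM. Neural progenitor genes had a median of 0.32 (adjusted p = 0.396). Cell cycle genes had a median of 0.03 (adjusted p = 0.789), and genes of actin and apical constriction a median of 0.03 (adjusted p = 0.733).

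Over single genes, edgeR called 0 of 11779 genes, and the smallest adjusted p was 1.00. At an unadjusted p below 0.05 there were 391 genes, against 589 by chance. DESeq2 called 9 genes and limma-voom 0. The genes with the smallest p were LOC100505012 (log2 fold change 3.12, SE 0.57), Tnfrsf19, a Wnt-regulated receptor (1.72, SE 0.37), and the calcium channel gene Cacna1g (1.43, SE 0.31) on the higher side. On the lower side they were Ankrd6 (-2.87, SE 0.72), Ccnh (-1.13, SE 0.30) and Mtch1 (-0.97, SE 0.26). The median standard error was 0.67 on the log2 scale, so that a change of 1 was mostly not detectable.

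**Figure D2:**
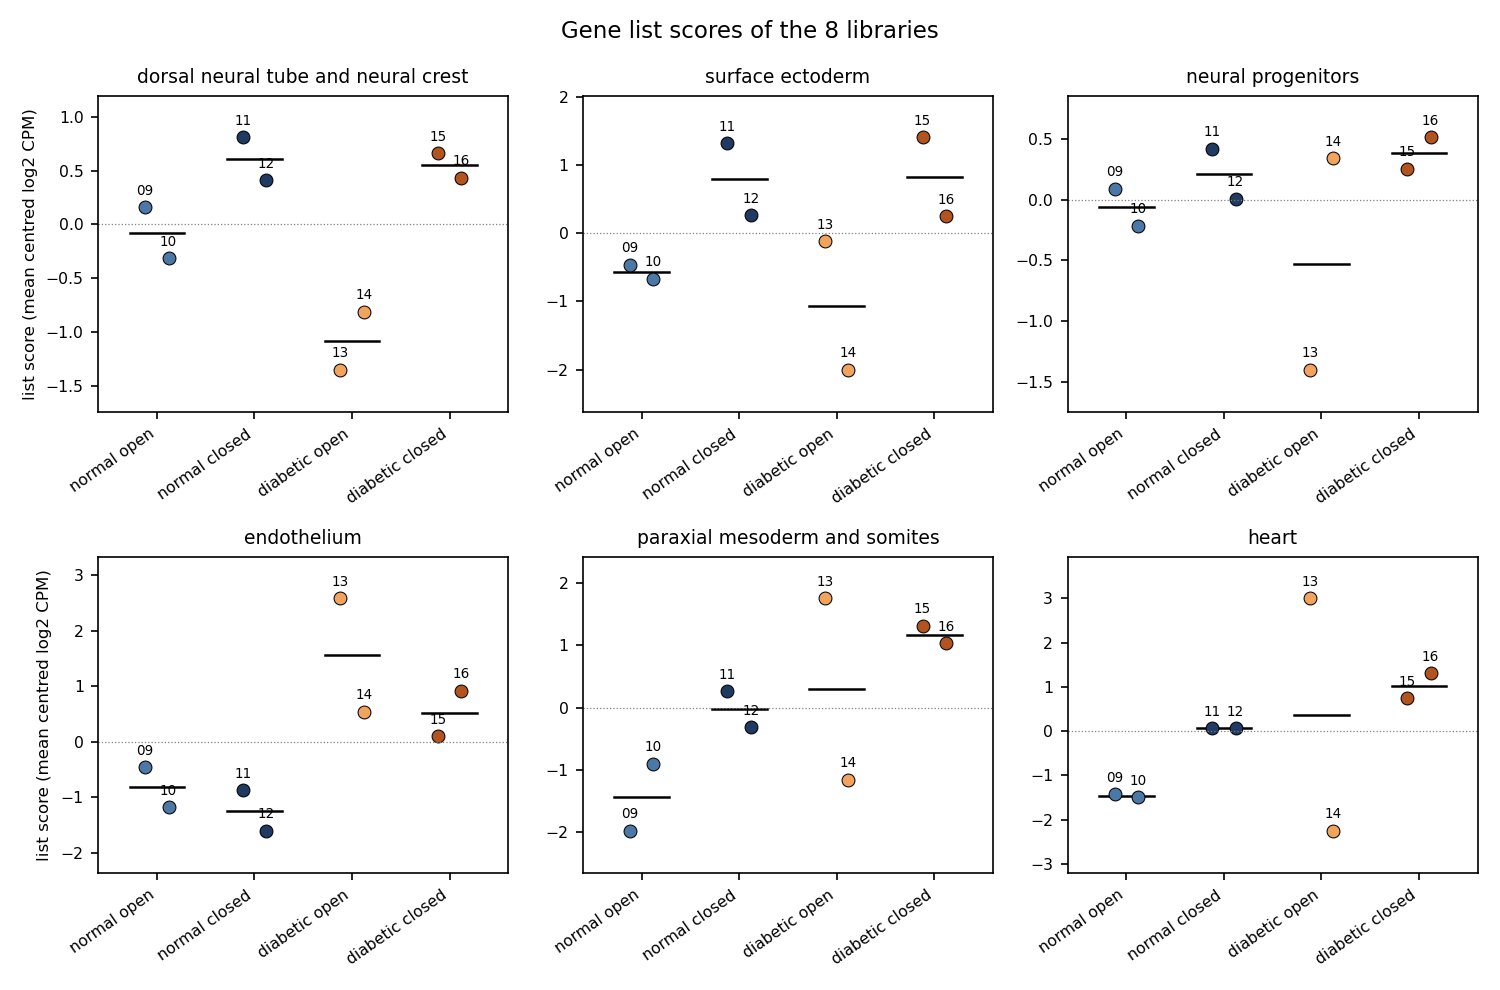
Each point is one library, labelled with its number, and each line is a group mean. The y axis is the list score, the mean log2 CPM of the members centred on the 8 libraries, for 6 lists. The endothelium score was above 0 in the 4 libraries of diabetic dams and below 0 in the 4 of normal dams.

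The second comparison asked how the tissue at the closure site differs between embryos of diabetic and of normal dams. Genes of endothelium and of paraxial mesoderm ranked higher with diabetic dams by camera at its preset correlation, and not at an estimated one (adjusted p = 0.432 each). Tek stood at 37.9 ± 45.6 CPM with diabetic and 0.692 ± 1.28 CPM with normal dams (SD, n = 4 each), and Egfl7 at 82.9 ± 41.8 and 40.5 ± 10.8 CPM. Pdgfra stood at 210 ± 176 and 51.9 ± 28.2 CPM, and Foxc2, a somite factor, at 100.1 ± 53.4 and 38.9 ± 26.8 CPM. None of these passed over all genes by edgeR, while DESeq2 called Tek and Pdgfra. Foxc2 was chosen after its values were seen.

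Of 15 measured endothelial genes, 13 had a positive fold change, with a median of 2.57 on the log2 scale (camera adjusted p = 1.09e-07, and adjusted p = 0.432 with an estimated correlation). Tek (0.0039) and Egfl7 (0.0426) passed when adjusted over the list alone. Over all genes 0 members passed by edgeR, while DESeq2 called Tek (adjusted p = 3.18e-05). The list of paraxial mesoderm and somites had 18 of 20 members positive, with a median of 1.76 (adjusted p = 1.98e-06, and adjusted p = 0.432 with an estimated correlation). The score of this list was positive in 3 of the 4 libraries of diabetic dams. In diabetic open library 14 it was -1.16, below 3 of the 4 libraries of normal dams (two-sided exact permutation p = 0.143, n = 4 each). Aldh1a2, which makes retinoic acid, stood at 156 ± 123 and 85.8 ± 39.1 CPM, and at 0.587 CPM in library 14, the lowest of the 8. The dorsal neural tube and neural crest list ranked lower, with 15 of 23 members negative and a median of -0.48 (adjusted p = 0.0212, and adjusted p = 0.432 with an estimated correlation). Within it, Twist1, also a mesoderm gene, stood higher, at 149 ± 109 against 39.8 ± 26.5 CPM, and Sox9 lower, at 48.6 ± 31.9 against 72.5 ± 32.7 CPM. Both genes were chosen after their values were seen. The dorsal list was no longer past the threshold without diabetic open library 13 (adjusted p = 0.198), without normal closed library 11 (0.124) or without normal open library 09 (0.113). The endothelium and somite lists stayed past it whichever library was left out, at most 0.000438 and 0.00468, both without library 13.

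Lists of other tissues did not pass. Primitive blood genes had a median of 5.10, or 4.29 with bounds (adjusted p = 0.0588), and Hba-x stood at 515 ± 483 CPM with diabetic and 16.1 ± 31.1 CPM with normal dams. Heart genes had a median of 2.62 (adjusted p = 0.112). Neural progenitor genes had a median of -0.11 (adjusted p = 0.166), and Sox2 stood at 319 ± 213 and 416 ± 116 CPM. The surface ectoderm list had a median of 0.38 but a mean of -0.02 and a downward test (adjusted p = 0.537). Among stress and metabolism lists, antioxidant defence had a median of 0.12 (adjusted p = 0.185), the unfolded protein response 0.08 (0.537), p53 response and apoptosis 0.45 (0.112), glycolysis and hypoxia response 0.16 (0.846), folate and one-carbon metabolism 0.06 (0.326) and oxidative phosphorylation -0.02 (0.537). Hspa5, a chaperone induced by endoplasmic reticulum stress, was at 1120 ± 264 and 1028 ± 128 CPM, and the peroxidase Prdx1 at 813 ± 50.9 and 766 ± 121 CPM. Genes with closure mutants had a median of -0.08 (adjusted p = 0.398). Pax3 was at 57.8 ± 56.9 CPM with diabetic and 85.7 ± 23.1 CPM with normal dams, and Vangl2 at 9.96 ± 2.63 and 16 ± 9.76 CPM. The glucose transporter gene Slc2a2 had 0 counts in all 8 libraries. It was 1 of 11446 genes without a count, among 26608 listed, and a lack of tags does not by itself show that a gene was not expressed.

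Over single genes, edgeR called 0 of 11779 genes (smallest adjusted p = 0.938). At an unadjusted p below 0.05 there were 536, against 589 by chance, and DESeq2 called 37 and limma-voom 0. The genes with the smallest p were Rps7, a ribosomal protein gene (log2 fold change 0.85, SE 0.16), Tek (5.84, SE 1.10) and the replication protein gene Rpa2 (1.37, SE 0.26) on the higher side. On the lower side they were LOC100503186 (-0.85, SE 0.20), Nphp4 (-1.49, SE 0.36) and Zfp598 (-5.82, SE 1.42). Zfp598 reached 91 CPM in normal closed library 12 and 66.1 CPM in normal open library 10, the libraries with Xist, and at most 2.21 CPM elsewhere. Genes that passed when adjusted over their list alone were Xist (0.0159), Rps7 (0.00997), Hba-x (0.00735), Gata4 (0.0174), Il17rd in the FGF list (0.00526) and Ube2c in the cell cycle list (0.0246).

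Within normal dams, 15 of 16 surface ectoderm genes (median 0.86) and 15 of 20 genes of paraxial mesoderm (median 1.04) were higher in closed tissue (camera adjusted p = 0.0442 each, and adjusted p = 0.855 each with an estimated correlation). The dorsal neural tube and neural crest list did not pass (17 of 23 positive, median 0.56, camera adjusted p = 0.335). The surface ectoderm call was kept only without normal closed library 12, and was lost without each of the 7 others (highest adjusted p = 0.928, without normal open library 09). The mesoderm call was lost without library 09 (0.952), 11 (0.832), 13 (0.0775), 15 (0.225) or 16 (0.254). Over single genes edgeR called 0, with 400 at an unadjusted p below 0.05, DESeq2 called 33 and limma-voom 0. Mapk7, a stress-activated kinase, was at 16.6 ± 3.96 CPM in closed and 0.135 ± 0.049 CPM in open tissue (n = 2 each). Shisa4 (16.6 ± 1.5 CPM) and Slc35a3 (9.32 ± 3.16 CPM) had no count in the open libraries, at least 86.9-fold and 50.2-fold lower by counting error alone. These bounds leave out genes lost from a library. Of genes with at least 50 counts in a normal open library, 3.12% and 6.44% had no count in its partner. Slc35a3 was at 12 and 39.5 CPM in diabetic open libraries 13 and 14. Sec11a, Znf512b and Ttc17 had the smallest p on the lower side, with Sec11a at 142 ± 4.44 against 291 ± 37.1 CPM. Pax3 was at 88.7 ± 17.3 and 82.7 ± 35.5 CPM.

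Within diabetic dams, dorsal neural tube and neural crest genes were higher in closed tissue in 16 of 23 cases (median 1.26, camera adjusted p = 4.2e-06, and adjusted p = 0.143 with an estimated correlation). Surface ectoderm (median 0.92, adjusted p = 0.0011) and caudal progenitors (median 1.17, adjusted p = 0.0174) ranked higher, and endothelium (median -1.31, adjusted p = 0.0011) and primitive blood (median -1.41, or -2.06 without members at no more than 3 counts in both groups, adjusted p = 0.015) lower, each with an adjusted p of 0.586 with an estimated correlation. The dorsal, endothelial, blood and caudal lists lost their calls without diabetic open library 13 (adjusted p = 0.115, 0.471, 0.297 and 0.201), and the surface ectoderm, blood and caudal lists without diabetic closed library 15 (0.238, 0.216 and 0.319). The surface ectoderm call was also lost without library 14 (0.116), and the caudal call without library 09 (0.0621), 11 (0.0664) or 12 (0.064). Pax3 was at 94.7 ± 62.4 CPM in closed and 20.9 ± 18.8 CPM in open tissue (log2 fold change 2.19, SE 0.72). Pdcd6, a calcium-binding protein gene, was at 404 ± 100.3 and 16.2 ± 17.2 CPM, and Arl4a at 117 ± 13.7 and 14.7 ± 4.38 CPM. Foxj1, a factor of ciliated cells, was at 11.9 ± 8.03 CPM in closed tissue and had no count in the open libraries. Piwil2, Gm6570 and the imprinted RNA Meg3 had the smallest p on the lower side, with Meg3 at 388 ± 39.8 against 1259 ± 828 CPM. By edgeR 0 genes passed (smallest adjusted p = 0.331), with 327 at an unadjusted p below 0.05, and DESeq2 called 47 and limma-voom 1, Pdcd6.

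In open tissue, 14 of 15 endothelial genes (median 2.49) and 18 of 20 genes of paraxial mesoderm (median 2.40, or 2.46 with bounds) were higher with diabetic dams (camera adjusted p = 0.000158 each, and adjusted p = 0.721 each with an estimated correlation). Dorsal neural genes ranked lower (median -0.81, or -0.91 with bounds, adjusted p = 0.00769, and adjusted p = 0.661 with an estimated correlation). All 3 lists lost their calls without diabetic open library 13 (adjusted p = 0.125, 0.542 and 0.468). The mesodermal and dorsal calls were also lost without normal open library 09 (0.378 and 0.264), and the dorsal call without normal closed library 11 (0.118) or 12 (0.128). Genes of other cell types stood higher too without passing: primitive blood had a median of 4.28, or 3.92 with bounds (adjusted p = 0.0757), and heart 3.44, or 3.96 with bounds (adjusted p = 0.209). Hba-x was at 926 ± 73.9 CPM with diabetic and 31.9 ± 43.7 CPM with normal dams. Pax3 was at 20.9 ± 18.8 CPM with diabetic and 82.7 ± 35.5 CPM with normal dams (log2 fold change -1.99, SE 0.72, adjusted p = 0.647). Slit1, an axon guidance gene (28.3 ± 3.21 CPM), and Foxj1 (24.7 ± 16.7 CPM) were counted with normal dams and had no count in either open library of diabetic dams. Pdcd6 was at 16.2 ± 17.2 and 506 ± 31.6 CPM. On the higher side were Slc35a3, Mapk7 (17.8 ± 2.39 CPM against 0.135 ± 0.049 CPM) and the autophagy gene Gabarap (487 ± 63.1 against 138 ± 29.8 CPM). By edgeR 0 genes passed (smallest adjusted p = 0.251), with 851 at an unadjusted p below 0.05 against 589 by chance. DESeq2 called 199 and limma-voom 1, Pdcd6.

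In closed tissue, endothelium (median 1.35, adjusted p = 2.96e-05), paraxial mesoderm (median 1.10, 0.00289), cytosolic ribosomal proteins (median 0.19, 0.00796), Hox paralogues 5 to 9 (median 1.56, 0.0352) and antioxidant defence (median 0.21, 0.0352) ranked higher with diabetic dams by camera. With an estimated correlation the smallest adjusted p was 0.651. The endothelial call was lost without normal closed library 12 (adjusted p = 0.345), and the ribosomal call without library 11 (0.884) or 15 (0.131). The mesodermal call was lost without library 09 (0.0619), 11 (0.123), 12 (0.598) or 15 (0.131). The antioxidant call was lost whichever library was left out (0.126 to 0.634), and the Hox call without any library except diabetic closed 16 (highest 0.914, without library 15). Beta-catenin (Ctnnb1) was at 85 ± 8.33 CPM with diabetic and 1296 ± 697 CPM with normal dams, and passed when adjusted over its list alone (0.0397). It was also at 79.7 CPM in normal open library 10. Hba-x was at 104 ± 141 and 0.334 ± 0.042 CPM, and Pax3 at 94.7 ± 62.4 and 88.7 ± 17.3 CPM. Mtdh and 1500012F01Rik on the higher side, and the Wnt secretion gene Wls and Fam193b on the lower, were the others with the smallest p. By edgeR 0 genes passed, with 138 at an unadjusted p below 0.05, and DESeq2 called 2 and limma-voom 0.

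Whether the region difference depended on the dam was tested as an interaction. No gene passed by edgeR (smallest adjusted p = 1.00), 440 had an unadjusted p below 0.05, and DESeq2 called 22 and limma-voom 1. No list passed either (smallest adjusted p = 0.111). The interaction was 2.09 on the log2 scale for Pax3 (SE 0.99, adjusted p = 1.00) and 5.11 for Pdcd6 (SE 0.95). Slit1, Foxj1, Slc35a3, Mapk7 and Piwil2 were the others with the smallest p. Across 11779 genes, which are not independent replicates, the region difference in normal and in diabetic dams had a Pearson r of 0.01 and a Spearman rho of 0.03. The diabetes difference in open and in closed tissue had an r of 0.08 and a rho of 0.12.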

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

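The fits without the 2 libraries with most genes at 0 and without the 2 with Xist were chosen after seeing the data. By edgeR 0 genes passed in the 7 comparisons, and 0 passed under DESeq2's size factors, total counts alone, a mean of at least 50 counts, models of only the libraries compared, the average of the simple contrasts and models without the other factor, wherever each was run. Without a filter the counts were 29 genes for closed against open tissue, 89 for the dams, 22 and 41 for closed against open tissue in normal and diabetic dams, 138 and 11 for the dams in open and closed tissue and 23 for the interaction. The DESeq2 test gave 9, 37, 33, 47, 199, 2 and 22 in the same order, and limma-voom 0, 0, 0, 1, 1, 0 and 1. In simulated counts 33.8% and 39.3% of DESeq2's calls were false. Among its calls in the real counts, the share with at least 1 library at 0 was 33.3%, 46%, 87.9%, 51.1%, 61.8%, 100% and 72.7% in that order. Of all genes tested it was 33.9%. Prior degrees of freedom give the weight that edgeR puts on a variance shared across genes. They were infinite without a filter, against 5.83 in the additive model and 5.87 in the model of 4 groups with it. Calls without a filter therefore rest on no variance of the single gene. Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 0 to 3 genes for closed against open tissue (3 without library 16), 0 to 2 for the dams (2 without library 15 or 16), 0 to 18 in normal dams (18 without library 09), 0 to 21 in diabetic dams (21 without library 14), 0 to 61 in open tissue (61 without library 14), 0 to 3 in closed tissue (3 without library 15 or 16) and 0 to 9 for the interaction (9 without library 14). Without the 2 libraries with most genes at 0 the counts were 20 in diabetic dams, 52 in open tissue and 17 for the interaction, and 0 in the other 4 comparisons. The cause was not tested.

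The numbers of lists past the threshold were 3, 3, 2, 5, 3, 5 and 0, and 0 in every comparison with an estimated correlation. Without a filter 0 lists passed in normal dams and 1 in closed tissue, and with a mean of at least 50 counts 8 passed in diabetic dams. Leaving out each library gave 3 to 7, 2 to 11, 0 to 3, 3 to 13, 0 to 11, 1 to 4 and 0 to 7 lists. The highest of these came without library 14 for the dams, diabetic dams, open tissue and the interaction. Without the 2 libraries with most genes at 0 the numbers were 7, 10, 1, 11, 11, 2 and 5, and without the 2 with Xist 7, 6, 2, 4, 3, 1 and 2. The correlation of the region differences was 0.0489 with a mean of at least 50 counts, 0.0518 without the 2 libraries with most genes at 0, and -0.0246 to 0.0791 with each library left out. That of the diabetes differences was 0.243 with a mean of at least 50 counts and -0.0136 (without library 13) to 0.114 with each left out. The cause was not tested. No list past the threshold changed direction in any of these fits. The spread between libraries (biological coefficient of variation 0.894 in the additive model) and 2 libraries per group limit the precision. The median standard error was 0.67 on the log2 scale in that model, and 0.43 for genes with a mean of at least 50 counts. Fitted to those genes alone, the additive model had a biological coefficient of variation of 0.567. The part that depth plays was not tested.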

Other observations

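The tests of a single library, of embryo sex, of the share of neural tube cells and of the genes counted after thinning were chosen after the results were seen. So were the test of scores that do not overlap and the splits for endothelium by region and the dorsal list by dam. The other splits and the test without the shared gene were set before they were run. Those for single lists concern lists that had passed in these same data.

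Markers of axial level differed between libraries of a group. These genes were chosen after their values were seen. Egr2, a gene of hindbrain rhombomeres, had 277 counts (32.5 CPM) in diabetic open library 14 and 0 in the other 7 libraries. Diabetic closed library 15 held Hoxb8 at 33.5 CPM and Hoxb9 at 63 CPM, genes of more posterior levels, against at most 1.82 and 1.68 CPM in the other 7. Hand1, a gene of lateral and heart mesoderm, had 1160 counts in diabetic open library 13 and 0 elsewhere, and Col3a1 was at 87.1 CPM there and at most 5.03 CPM in the others.

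Thinned to 5041586 counts per library, 11808 ± 908 genes had a count in closed and 10476 ± 718 in open tissue (n = 4 each, two-sided exact permutation p = 0.143). The counts were 11564 ± 1301 with diabetic and 10721 ± 597 with normal dams (exact permutation p = 0.2). Of 84 cytosolic ribosomal protein genes, 50 had a count in any library.

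Endothelial and somite genes ranked higher with diabetic dams (the somite score not in diabetic open library 14, at -1.16). Without diabetic open library 13 both lists stayed past the threshold (camera adjusted p = 0.000438 for endothelium and 0.00468 for somites). Without the 2 libraries with Xist, over both regions together, the adjusted p was 2.89e-05 for endothelium. All are at the preset correlation, and both lists had 0.432 with all libraries and an estimated one. Other splits of the libraries also gave small p values at the preset correlation. Staying past the threshold therefore cannot decide whether library 13 alone accounts for the pattern. For the endothelium list 1 of the 35 splits of the libraries, the real one, gave as small a p (-log10 p of 8.48, highest other 6.51), while for the somite list 7 of 35 did (6.92, highest other 13.9), so that chance is not excluded for the somite list. For endothelium 1 of 35 is the smallest share possible, but the list was picked among 33 in these same data. Chance is therefore not excluded there either. The exact permutation test on the score difference between dams gave an adjusted p of 0.314. It cannot decide, because its smallest possible p of 0.0286 passes over 33 lists only if many lists reach it. A lower share of neural tube cells in the sections could raise both. The endothelium score minus the surface ectoderm score was 1.15 ± 1.88 with diabetic and -1.15 ± 1.05 with normal dams (two-sided exact permutation p = 0.114, n = 4 each). That test assumes that surface ectoderm would rise alike, which need not hold. Diabetic open library 13 had the lowest neural progenitor score (-1.40), an endothelium score of 2.58 and a surface ectoderm score of -0.114. A lower share of neural tube cells therefore cannot be told apart with these 8 libraries. More vessel tissue in the sections and a difference due to the dam both stay open.

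Dorsal neural tube and surface ectoderm genes ranked higher in closed tissue over both kinds of dam together. Within normal dams alone the dorsal list did not pass (camera adjusted p = 0.335). Without Tcfap2a, the gene both lists hold, the larger camera adjusted p was 0.0015, so that gene alone does not carry the pattern at the preset correlation. Without diabetic open library 13 the larger adjusted p was 0.0364. Other splits of the libraries also gave small p values, so this cannot decide whether library 13 carries the pattern. With all libraries and an estimated correlation the adjusted p was 0.279 and 0.602. For the dorsal list 1 of 35 splits, the real one, gave as small a p (-log10 p of 5.35, highest other 4.42), and for surface ectoderm 4 of 35 did (5.07, highest other 6.64), which does not exclude chance. The share for the dorsal list is the smallest possible, but the list was picked among 33 in these same data. Chance is therefore not excluded there either. The exact permutation test on the score difference between regions gave an adjusted p of 0.269. It cannot decide, because its smallest possible p of 0.0286 passes over 33 lists only if many lists reach it. More surface ectoderm left on sections of the closed tube stays open beside a difference of the region, and was not tested. Closed tissue was cut behind open tissue, so closure cannot be told apart from axial level. Hox paralogues 5 to 9 had 6 of 6 members positive in closed tissue (median 1.30, camera adjusted p = 0.198). The closed libraries were not alike in this: the list score was 3.05 in library 15, and 0.37, -0.155 and -0.23 in libraries 16, 11 and 12. In open libraries 13, 14, 09 and 10 it was 1.03, -1.78, -0.501 and -1.79. Hox paralogues 1 to 4 had 5 positive and 5 negative (median 0.08, adjusted p = 0.841).

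Xist was lower with diabetic dams. Different sex of the embryos may account for it: Ddx3y was at most 0.849 CPM in the 2 libraries with Xist and at least 192 CPM in the other 6. Each library may then hold embryos of mostly 1 sex, unequally between the dams.

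The numbers of lists past the threshold were no larger than in many other splits. For closed against open tissue 3 lists passed, which 21 of 35 splits reached (highest other 10), and for the dams 3 lists passed, which 23 of 35 reached (highest other 16). Chance is not excluded for either number. With 0 genes past the edgeR threshold in both comparisons (391 and 536 at an unadjusted p below 0.05, 9 and 37 by DESeq2, 0 by limma-voom), 35 of 35 splits reach as many by construction (highest other 1 in each). This says nothing about chance. Nor is chance excluded for the endothelium list in closed against open tissue, where 4 of 35 splits gave as small a p (-log10 p of 4.21, highest other 7.44), or for the dorsal list between dams, where 4 of 35 did (2.71, highest other 4.48). The split with 16 lists set diabetic closed library 15 and diabetic open library 14 with both normal open libraries, and may reflect a structure of the samples other than the groups, which was not tested.

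The scores of the dorsal, surface ectoderm and closure mutant lists did not overlap between closed and open tissue, nor did those of endothelium and Hox paralogues 1 to 4 between dams. That is 3 and 2 of 33 lists, where chance gives 2.86% of lists. None passed after adjustment over the lists (smallest adjusted p of the exact permutation test 0.269 and 0.314). The smallest p that this test can give here is 0.0286. Adjusted over 33 lists, it could pass only if many lists reached it at once. The failure to pass therefore cannot decide whether these scores differ.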
